A study of Homo sapiens with 8 samples.

How the data were processed

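The series held 8 RNA sequencing libraries of a human leukaemia line, 4 labelled as carrying an empty vector (MOCK) and 4 labelled as carrying the mutant construct (RRM2_OE). Groups and replicate numbers were taken from the sample labels, and every column of the tables was matched to a sample by its name. Per the labels' protocols, libraries were made with a stranded poly(A) kit from 200 ng of total RNA. The submitters' processing notes name bcl2fastq 2.18.0.12, TopHat2, HTSeq 0.11.2 and the genome build hg19 (GRCh37), without roles or order. The version of TopHat2, the gene annotation and the strand setting of the counting are not given in the sources used here.

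The deposited count table gave whole-number read counts per Ensembl gene for 34618 genes, of which 7832 had 0 counts in every library. The authors' RPKM table was recomputed to within 4.7e-06 from the counts, the column totals and the exon length in base pairs deposited beside each gene (per the file headers). Coordinates are those of the deposited tables. Symbols were assigned by Ensembl ID for 32562 genes from a table of current names and for 299 more from GENCODE 29, and 1757 IDs were left unnamed. Of 803 entries in the gene lists, 796 were found by current or older symbol. UHRF1, MRC1, BOP1, CCL3, CCL4, CCL5 and TRAC were not matched and were not analysed here.

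Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr with its defaults kept 15286 genes, TMM factors scaled the libraries, and robust quasi-likelihood F tests compared RRM2_OE with MOCK with no further covariate. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05, and standard errors of log2 fold changes were computed as the log2 fold change over the square root of F. Levels are CPM on the TMM-scaled library sizes. The typical biological coefficient of variation was 7.2%, and 2.64% once odd and even replicate numbers were separated. The 27 gene lists, the rule for named genes, the tests and most alternatives were fixed before the data were examined. Lists with at least 5 tested genes, 26 in all, were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. Adjustment of their p-values was over the 26 lists, and camera with an estimated correlation and fry were run beside it. Camera called 15 lists higher and 6 lower, and with an estimated correlation the p53, NF-kB, G1/S and T and NK lists remained called. With the block and an estimated correlation together no list passed (lowest camera adjusted p = 0.0519, the p53 list). The block leaves few residual degrees of freedom, on which camera relies when the correlation is estimated. This joint test therefore has little power, and a list that misses its threshold decides little. With the odd/even term in place of the block, 11 lists remained called.

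The rule named RRM2, RRM1 and RRM2B, then the 6 largest rises and the 6 largest falls among called genes with protein-coding-like symbols, a mean of at least 5 CPM and no overlap between the groups, then the 2 members of each list with the smallest adjusted p below 0.05, or 3 where camera called the list, 83 genes in all. A gene that the rule names is not reported here. Other genes named in the text were chosen after their values were seen. Of the 83 genes, 12 have a span that overlaps another measured gene on the same strand and 35 on the opposite strand. How the authors' counting treated reads in such overlaps is not stated, so values of CASP1 (with CARD16), RPS13 (with PIK3C2A), TRIM22, NFKBIZ and HBG2 carry that uncertainty.

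Whether replicate numbers pair the libraries was checked on deviations of log2 CPM from the group means. The same-numbered libraries correlated at 0.25, 0.23, 0.22 and 0.23, so that all 4 pairs passed 0.1, although only 1 of the 8 libraries correlated best with its own number. The structure behind these correlations was odd against even numbers: libraries of the other group with the same parity correlated at 0.22 to 0.29 and those with the other parity at -0.28 to -0.21. The main test included neither replicate number nor parity, and each entered only as an alternative. Within a group, libraries of like parity differed by less than those of unlike parity (chi-square per degree of freedom 1.47 to 2.9 against 6.18 to 12, over genes with at least 20 counts in a pair). All pairs differed by more than sampling noise, so none were merged. That excess does not show that libraries of like parity were separate cultures, so n = 4 may overstate the number of independent samples.

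Alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile factors, library sizes only, no low count filter, a filter of 1 CPM in 4 libraries, replicate number as a block, limma on log2 RPKM with pseudocounts of 1 and 0.1, an adjusted p of 0.01, a fold change of 2, glmTreat against 1.2-fold, a prior count of 0.5 for camera, and leaving out each library in turn. An odd/even term, replicates 1 and 3 or 2 and 4 alone, sums of the odd and of the even libraries, fits without the 13 mitochondrial genes, and list tests that join the block or the odd/even term with an estimated correlation were added after seeing the data.

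The procedure was tested on simulated counts for 15286 genes drawn from the means, dispersions and library sizes of these libraries, with 200 changed genes. For this comparison edgeR recovered 46% of genes changed 1.25-fold, 62% at 1.5-fold, 92% at 2-fold and 98% at 3-fold, with 11 false calls, so small changes are often missed. Of 100 random lists, 1 passed 0.05 with camera. The simulated genes were drawn independently of each other and without the odd/even structure. The recovery and false calls therefore describe libraries without that structure. The share of random lists does not show how camera behaves on lists of correlated genes, such as the ribosomal protein list with an estimated correlation of 0.31. Closing tests and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. GC content came from GENCODE 29 transcripts matched by gene ID.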

Results

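Gene expression was measured by stranded, poly(A)-selected RNA sequencing in 8 libraries of cells labelled THP1, a human acute monocytic leukaemia line that carries a KMT2A fusion. The label was kept, but all 8 libraries expressed genes not commonly described for that line, among them CDKN2A at 44.6 to 56.3 CPM. The cells may include or be another line, a hypothesis set out in the last part. The 4 MOCK libraries came from cells with an empty vector and the 4 RRM2_OE libraries from cells with the iRxI/AxA mutant, which the labels also call RRM2 OE, read here as RRM2 overexpression. All cultures received doxycycline at 2 µg/mL, so the drug itself did not differ between the groups. RRM2 is the small subunit of ribonucleotide reductase, the enzyme that makes deoxyribonucleotides for DNA synthesis, and its RxI motif, to which the mutant's name is taken to refer, is bound by cyclin F ahead of RRM2 degradation. The comparison asked which genes change when this mutant is introduced, in a series concerned with dNTP balance and blocked differentiation in acute myeloid leukaemia. Enzyme activity, protein and dNTP levels are not part of these data. Library totals lay between 10994255 and 11686152 counts. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these libraries.

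RRM2 transcripts rose from 123 ± 5.35 CPM in MOCK to 225 ± 8.33 CPM in RRM2_OE (mean ± SD, n = 4 each), a 1.82-fold increase (log2 fold change 0.87, SE 0.05, adjusted p = 5.64e-07, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The 4 RRM2_OE libraries, at 215 to 236 CPM, all lay above the 4 MOCK libraries, at 116 to 128 CPM. RRM2 (ENSG00000171848) lies on chromosome 2 at 10262455 to 10271545 of hg19. Counts per gene do not separate the introduced from the resident copy. RRM1, the large subunit, rose by 0.32 on the log2 scale, and RRM2B, a p53-inducible small subunit, rose by 0.59. Cyclin F (CCNF) gave a log2 fold change of -0.02 (adjusted p = 0.860, edgeR).

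Across the 15286 genes tested, 1133 were higher and 829 lower in RRM2_OE at an adjusted p below 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), and 79 of the rises and 19 of the falls reached 2-fold. The largest rises by the naming rule were VWCE, a von Willebrand factor C domain protein, at 1.68 on the log2 scale, PLK2, a stress-responsive kinase, at 1.59, GDF15, a stress cytokine, at 1.54, SCN4B, a sodium channel subunit, at 1.54, FPR1, a formyl peptide receptor of phagocytes, at 1.54, and CDKN1A, which encodes the cell cycle inhibitor p21, at 1.52. CDKN1A (chromosome 6, 36644305 to 36655116) went from 294 ± 53.9 to 844 ± 175 CPM (mean ± SD, n = 4). FPR1 overlaps FPR2 and FPR3 on the opposite strand, and the strand setting of the counting is not stated. The largest falls were IGLL1, a surrogate light chain gene of B cell precursors, at -1.47, MPO, the myeloperoxidase of azurophil granules, at -1.40, ADD2, a membrane skeleton protein, at -1.28, PRTN3, the granule protease proteinase 3, at -1.20, PIF1, a DNA helicase, at -1.18, and TNXB, an extracellular matrix protein that shares sequence with a pseudogene copy and is therefore uncertain, at -1.13. MPO (chromosome 17, 56347217 to 56358296) went from 1225 ± 147 to 466 ± 52.99 CPM and PRTN3 from 2395 ± 262 to 1043 ± 109 CPM (mean ± SD, n = 4). With replicate number as a block, 2303 genes were higher and 2143 lower, and 1961 of the 1962 genes called without the block were among them. Leaving out MOCK replicate 2 left 542 genes lower, and leaving out RRM2_OE replicate 1 or RRM2_OE replicate 3 left 545. Rises made up 57.7% of the calls on counts and 68.4% on log2(RPKM + 1).

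**Figure D1:**
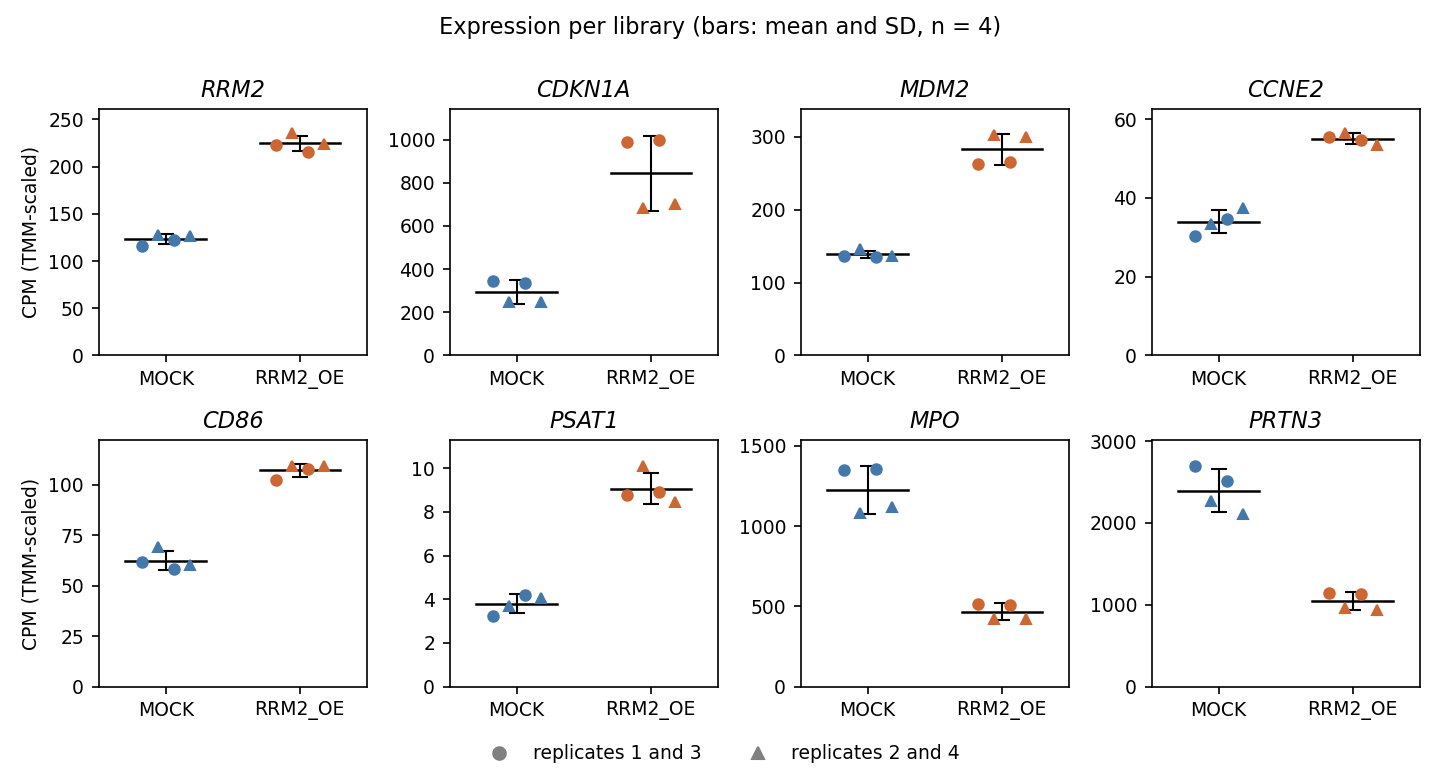
Expression per library of RRM2, the p53 targets CDKN1A and MDM2, the G1/S cyclin CCNE2, the co-stimulatory ligand CD86, the serine synthesis enzyme PSAT1 and the granule genes MPO and PRTN3, in CPM (y axes start at 0). Each point is a library (circles, replicates 1 and 3; triangles, replicates 2 and 4), and bars give the mean and SD of 4 libraries; for every gene shown the groups do not overlap, for example 294 CPM against 844 CPM on average for CDKN1A and 1225 CPM against 466 CPM for MPO.

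The 8 libraries also differed along a line that crossed the groups. The first principal component of log2 CPM, with 33.5% of the variance, separated the groups, and the second, with 24.7%, separated replicates 1 and 3 from replicates 2 and 4 in both groups. In a fit with both terms, 2360 genes were higher and 2292 lower in the odd-numbered libraries, among them the mitochondrial genes MT-ATP8 at 1.60 and MT-ND6 at -0.80 on the log2 scale. Mitochondrial genes took 8.02% to 9.51% of the counts in the odd-numbered libraries and 6.43% to 7.69% in the even-numbered ones, without overlap. Each group held 2 libraries of either kind. Of the genes called between RRM2_OE and MOCK, all 1961 with a value in both sets had that direction in replicates 1 and 3 and in replicates 2 and 4, which their choice over the same libraries largely builds in.

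**Figure D2:**
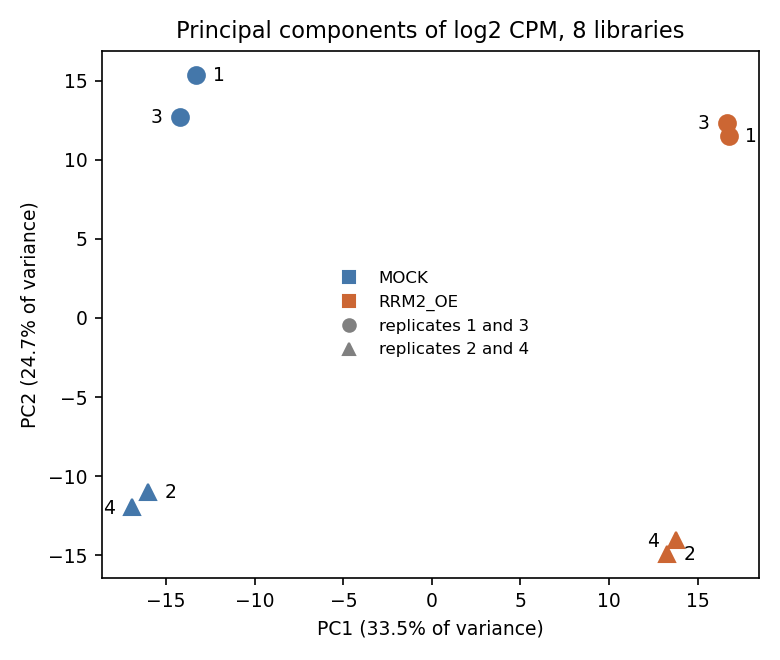
First (x axis, 33.5% of variance) and second (y axis, 24.7% of variance) principal components of log2 CPM for the 4 MOCK and 4 RRM2_OE libraries. Colours give the group, symbols separate replicates 1 and 3 from replicates 2 and 4, and digits give the replicate number; the groups separate along x and odd from even numbers along y.

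Genes of the p53 response rose together. Of 27 tested p53 pathway targets, 22 rose and 0 fell (24 rose adjusted over the list alone), with a median log2 fold change of 0.57. The E3 ligase MDM2, which p53 induces as its own antagonist, rose from 139 ± 4.90 to 283 ± 21.6 CPM (mean ± SD, n = 4), the AKT inhibitor PHLDA3 rose by 1.16 and GDF15 by 1.54 on the log2 scale. The pro-apoptotic genes BBC3 (0.97), PMAIP1 (0.81) and FAS (0.70) rose as well, while CCNG1 gave -0.01 and did not pass. The list was higher by camera (adjusted p = 4.25e-20, and adjusted p = 0.001 with an estimated correlation). It missed the threshold with the block and an estimated correlation together (camera adjusted p = 0.0519), a test with little power. The median was 0.57 in replicates 1 and 3 and 0.56 in replicates 2 and 4.

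Genes of the G1/S transition and DNA replication were higher. Of 41 tested, 22 rose and 0 fell (25 rose adjusted over the list alone), with a median of 0.26. The G1/S cyclin CCNE2 rose by 0.70, the sliding clamp PCNA by 0.59 and the ubiquitin ligase adaptor DTL by 0.44 on the log2 scale. The helicase subunits MCM2 (0.02) and MCM7 (0.06) did not pass. The camera test gave adjusted p = 4.12e-14, and adjusted p = 0.022 with an estimated correlation, or adjusted p = 0.093 with the block as well. With the block, 28 of these genes rose and 1 fell. Of 28 dNTP supply genes, 8 rose and 0 fell (8 rose adjusted over the list alone), with a median of 0.08; besides RRM2, RRM1 and RRM2B they included thymidylate synthase (TYMS, 0.37), TK1 (0.52) and the dNTP hydrolase SAMHD1 (0.25). With the block, 10 dNTP supply genes rose and 1 fell. This list was higher by camera (adjusted p = 6.13e-04, but adjusted p = 0.057 with an estimated correlation). Of 42 DNA damage checkpoint and repair genes, 15 rose and 1 fell (20 and 3 adjusted over the list alone), with a median of 0.16. The Fanconi anaemia gene FANCI rose by 0.40, the exonuclease EXO1 by 0.64 and the recombination gene RAD54L by 0.38, while the kinase ATM fell by 0.17 on the log2 scale. With the block, 21 repair genes rose and 5 fell. For this list camera gave adjusted p = 1.79e-04, and adjusted p = 0.092 with an estimated correlation.

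Mitotic genes went both ways. Of 42 tested G2/M genes, 3 rose and 9 fell (5 and 9 adjusted over the list alone), with a median of -0.02. PLK1, the mitotic entry kinase, fell from 76.4 ± 3.55 to 52.2 ± 3.58 CPM (mean ± SD, n = 4), and CDC20, an activator of the anaphase-promoting complex, fell by 0.49 on the log2 scale. CENPF (-0.59) and ASPM (-0.43) also fell, and the 3 that rose were NDC80 (0.31), AURKB (0.30) and NUSAP1 (0.17). With the block, 8 mitotic genes rose and 14 fell. The list as a whole was not called (camera adjusted p = 0.134, adjusted p = 0.543 with an estimated correlation).

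Part of the monocyte and macrophage genes rose, and part of the granule genes fell. Of 43 tested monocyte and macrophage genes, 19 rose and 0 fell (24 rose adjusted over the list alone), with a median of 0.25. CD86, a co-stimulatory ligand of antigen-presenting cells, rose from 62.4 ± 4.77 to 107 ± 3.30 CPM (mean ± SD, n = 4). The IgG receptor FCGR2A rose by 0.76 and the receptor TREM1 by 0.66 on the log2 scale. The calprotectin subunits S100A8 (1.16) and S100A9 (0.66), CD14 (0.41) and LYZ (0.37) rose, while CD163 (-0.14) and CD36 (-0.00) did not pass. Higher by camera (adjusted p = 6.29e-10), the list reached adjusted p = 0.056 with an estimated correlation. Of 26 tested granulocyte and progenitor granule genes, 5 rose and 12 fell (5 and 13 adjusted over the list alone), with a median of -0.26. Besides MPO and PRTN3, the azurophil granule genes AZU1 and ELANE fell, by 0.72 and 1.06 on the log2 scale, as did the eosinophil peroxidase EPX (-0.69) and the granulocytic transcription factor CEBPE (-0.66). The 5 that rose were CD177 (1.299), BPI (0.36), CLC (0.31), CST7 (0.29) and CD38 (0.23), of which CD177 is a neutrophil surface protein and BPI a granule protein. The list was lower by camera (adjusted p = 4.91e-04, but adjusted p = 0.115 with an estimated correlation).

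Markers of other lineages were measured beside these groups. Of 8 tested T and NK genes, 6 rose and 0 fell (7 rose adjusted over the list alone), with a median of 0.58, and 7 of the 8 were at 1 CPM or more in MOCK already. IL7R, the interleukin 7 receptor, rose from 85.3 ± 3.02 to 131 ± 3.47 CPM (mean ± SD, n = 4), the T cell receptor component CD3D rose by 0.55, the cytolytic protein PRF1 by 0.36 and CD8A by 1.91 on the log2 scale, the last from 0.33 to 1.28 CPM. Camera gave adjusted p = 2.05e-07, and adjusted p = 0.012 with an estimated correlation, or adjusted p = 0.093 with the block as well. Of 17 erythroid and megakaryocyte genes, 2 rose and 4 fell (2 and 6 adjusted over the list alone), with a median of -0.19. All 17 were at 1 CPM or more in MOCK, and 12 were at 10 CPM or more in every library. The haem synthesis gene ALAS2 fell by 0.66 and the fetal globin gene HBG2, whose span overlaps 7 other genes on its strand, fell by 0.64, while the platelet chemokine PPBP rose by 0.91. With the block, 2 rose and 8 fell. This list was lower by camera (adjusted p = 0.016, but adjusted p = 0.115 with an estimated correlation), and not when genes had to reach 1 CPM in 4 libraries (adjusted p = 0.093). Of 5 B and plasma cell genes, 2 rose and 1 fell (2 and 1 adjusted over the list alone), 4 being at 1 CPM or more in MOCK: IGLL1 fell, and CD79A (0.63) and FCRL1 (1.497) rose, the latter from 0.82 to 2.34 CPM. The list was not called (camera adjusted p = 0.522, adjusted p = 0.704 with an estimated correlation), and its median of 0.23 was -0.07 in replicates 1 and 3 and 0.57 in replicates 2 and 4. Only 4 of the epithelial, fibroblast and HEK293 genes could be tested, all at 1 CPM or more in MOCK; FN1, which macrophages also make, rose by 0.85 and PDGFRB by 0.42 (2 of the 4 rose and 0 fell, likewise adjusted over the list alone), with a median of 0.28 and no camera test. The PDGFRB call was lost on leaving out any of 5 single libraries (adjusted p up to 0.092, edgeR).

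**Figure D3:**
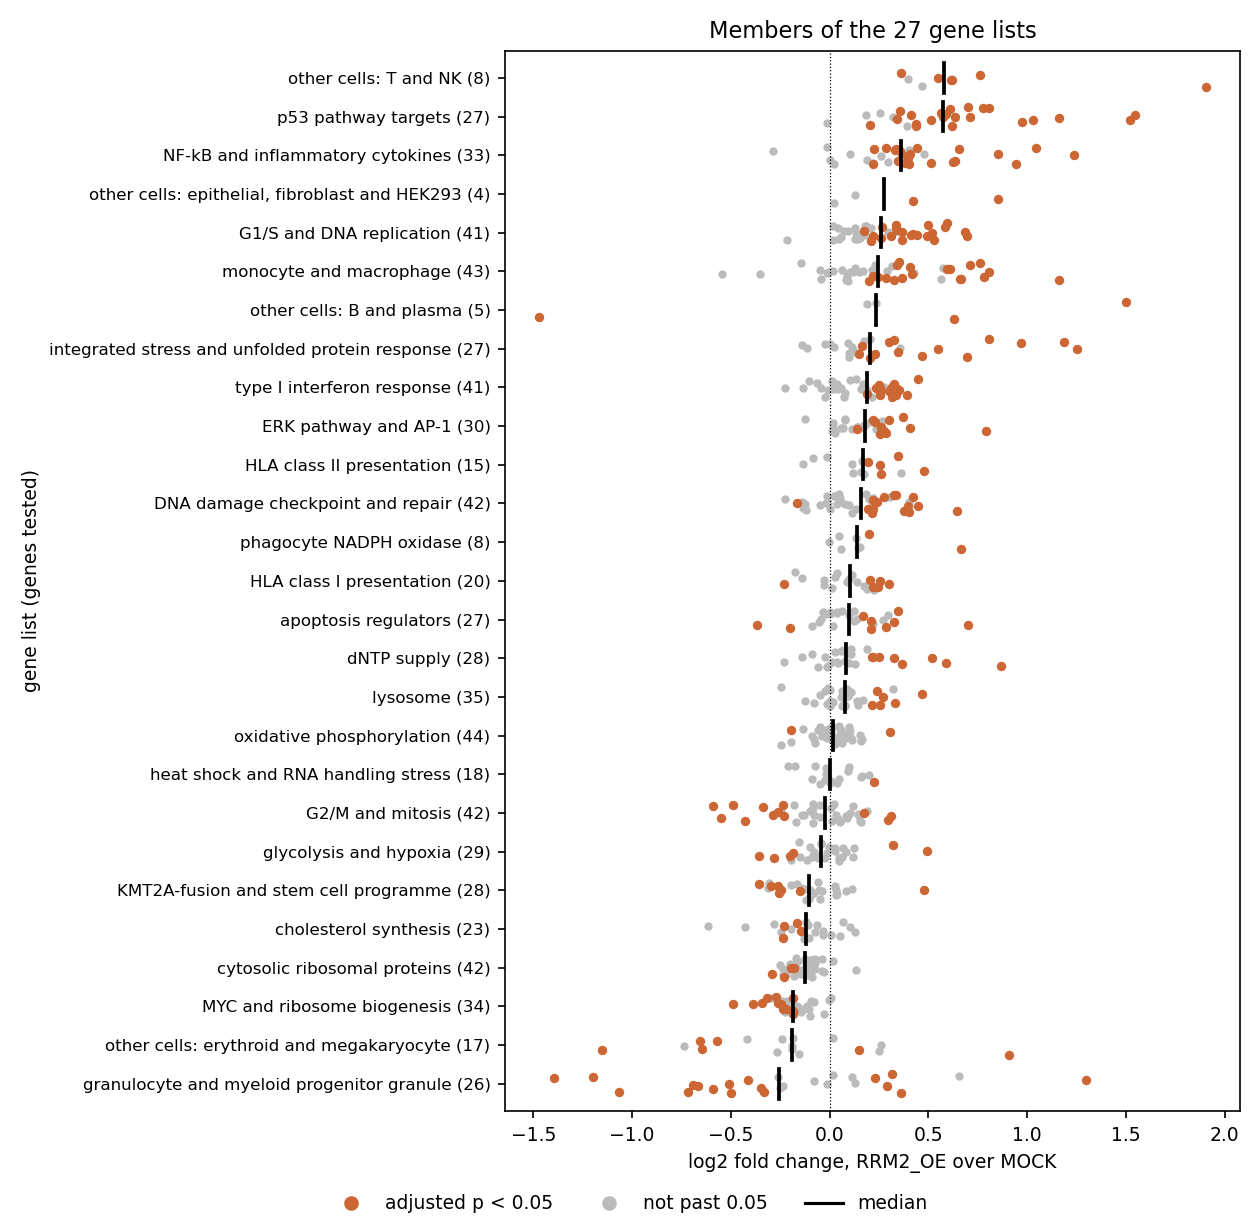
Log2 fold changes (x axis, RRM2_OE over MOCK) of every tested member of the 27 gene lists (y axis, with the number of genes tested). Orange points passed an adjusted p of 0.05 (edgeR), grey points did not, and black bars give medians; the p53 targets have a median of 0.57 and the granule genes, which spread from MPO at -1.40 to CD177 at 1.299, a median of -0.26.

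Inflammatory and signalling lists were called higher at the preset correlation. Of 33 tested NF-kB targets and cytokines, 21 rose and 0 fell (28 rose adjusted over the list alone), with a median of 0.36. IL1B, an inflammatory cytokine, rose from 108 ± 3.71 to 171 ± 2.68 CPM (mean ± SD, n = 4), the nuclear regulator NFKBIZ rose by 0.63 and the chemokine CCL24 by 0.85 on the log2 scale, and CXCL1 (1.24) and EBI3 (1.05) rose further. By camera the list was higher (adjusted p = 2.79e-15), with adjusted p = 0.0043 with an estimated correlation, or adjusted p = 0.068 with the block as well. Of 41 interferon-stimulated genes, 18 rose and 0 fell (21 rose adjusted over the list alone), with a median of 0.19; the antiviral genes OAS3 (0.31), TRIM22 (0.32) and CMPK2 (0.39) were among them, whereas STAT2 (0.04) did not pass. With the block, 24 interferon-stimulated genes rose and 1 fell. Their camera test gave adjusted p = 9.21e-08, and adjusted p = 0.057 with an estimated correlation. Of 30 ERK pathway and AP-1 genes, 11 rose and 0 fell (11 rose adjusted over the list alone), with a median of 0.18, among them the stress-induced factor ATF3 (0.79), the feedback inhibitor SPRY1 (0.41), IER3 (0.37) and PHLDA1 (0.30). That list was higher by camera (adjusted p = 4.92e-07, but adjusted p = 0.115 with an estimated correlation).

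A minority of antigen presentation genes passed the test. Of 15 class II genes, 5 rose and 0 fell (7 rose adjusted over the list alone), with a median of 0.17; the peptide editor HLA-DMB rose by 0.48, HLA-DRA by 0.26 and HLA-DRB5 by 0.25, the last with near-identical copies that make its counts uncertain. With the block, 12 class II genes rose and 1 fell. The class II camera test gave adjusted p = 0.002, and adjusted p = 0.059 with an estimated correlation. Of 20 class I genes, 5 rose and 1 fell (6 and 1 adjusted over the list alone), with a median of 0.11: the peptide transporter TAP1 rose by 0.30 and the proteasome activator PSME2 by 0.20, and the chaperone CALR fell by 0.23. With the block, 10 class I genes rose and 1 fell. The class I list was higher by camera (adjusted p = 0.029, but adjusted p = 0.088 with an estimated correlation), and not without RRM2_OE replicate 1 (adjusted p = 0.051), without RRM2_OE replicate 2 (adjusted p = 0.060) or in replicates 1 and 3 alone (adjusted p = 0.057). Of 8 NADPH oxidase genes, 2 rose and 0 fell (3 rose adjusted over the list alone), with a median of 0.14: NCF1, which has near-identical copies, rose by 0.67, and CYBB, the catalytic subunit, rose by 0.20 with overlapping groups. With the block, 4 of the 8 oxidase genes rose. The CYBB call was lost on leaving out any of 6 single libraries (adjusted p up to 0.104, edgeR). Their camera test gave adjusted p = 0.026, adjusted p = 0.222 with an estimated correlation and adjusted p = 0.062 without MOCK replicate 4.

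Stress, apoptosis and lysosomal lists were called higher at the preset correlation. Of 27 integrated stress and unfolded protein response genes, 14 rose and 0 fell (16 and 1 adjusted over the list alone), with a median of 0.20. PSAT1 and PHGDH, enzymes of serine synthesis, rose by 1.252 and 0.97 on the log2 scale, the pseudokinase TRIB3 by 0.70 and the transcription factor DDIT3 by 0.46, while the chaperones HSPA5 (-0.02) and HSP90B1 (-0.11) did not pass. With the block, 20 of these stress response genes rose and 2 fell. The camera test gave adjusted p = 9.21e-08, and adjusted p = 0.056 with an estimated correlation. Of 27 apoptosis regulators outside the p53 list, 7 rose and 2 fell (8 and 2 adjusted over the list alone), with a median of 0.10: the death ligand TNFSF10 rose by 0.70 and CASP1 by 0.29, and CASP6 fell by 0.37. This list was higher by camera (adjusted p = 0.032, but adjusted p = 0.115 with an estimated correlation), and not without MOCK replicate 1 (adjusted p = 0.050), without RRM2_OE replicate 2 (adjusted p = 0.080) or in replicates 1 and 3 alone (adjusted p = 0.125). Of 35 lysosomal genes, 6 rose and 0 fell (6 rose adjusted over the list alone), with a median of 0.08; the hydrolases FUCA1 (0.47) and NEU1 (0.27) were among those that rose. With the block, 15 lysosomal genes rose and 2 fell. The lysosomal list was higher by camera (adjusted p = 0.0042, but adjusted p = 0.059 with an estimated correlation).

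Lists of growth and of immature cells were called lower at the preset correlation, with a minority of their members passing without the block. Of 34 tested MYC and ribosome biogenesis genes, 0 rose and 13 fell (16 fell adjusted over the list alone), with a median of -0.19. MYC itself fell from 290 ± 12.7 to 207 ± 5.71 CPM (mean ± SD, n = 4), and POLR1C, a subunit of RNA polymerases I and III, and the nucleolar protein UTP20 fell by 0.39 and 0.34 on the log2 scale. With the block, 27 of the 34 fell. The camera test gave adjusted p = 1.97e-08, and adjusted p = 0.057 with an estimated correlation. Of 42 cytosolic ribosomal protein genes, 0 rose and 4 fell (3 fell adjusted over the list alone), with a median of -0.13; RPS23 gave -0.29, RPL22 -0.23 and RPS13 -0.19. The calls of RPS23 and RPS13 were lost on leaving out any of 4 and any of 6 single libraries (adjusted p up to 0.060 and 0.072, edgeR), whereas with the block 30 of the 42 fell. The ribosomal protein list was lower by camera (adjusted p = 1.66e-05, but adjusted p = 0.244 with an estimated correlation). Of 28 genes of KMT2A fusions and stem cells, 1 rose and 6 fell (1 and 7 adjusted over the list alone), with a median of -0.10. The cell cycle kinase CDK6 and the transcription factor MYB, both linked to immature myeloid cells, and the demethylase-family gene JMJD1C each fell, with log2 fold changes of -0.25, -0.25 and -0.26, HOXA9 (-0.08) and MEIS1 (0.03) did not pass, and the progenitor marker CD34 rose by 0.48. With the block, 2 rose and 9 fell. That list was lower by camera (adjusted p = 0.0026, but adjusted p = 0.056 with an estimated correlation).

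Of the metabolic and handling-stress lists, camera called cholesterol synthesis. Of 23 cholesterol synthesis genes, 0 rose and 4 fell (8 fell adjusted over the list alone), with a median of -0.12; LSS gave -0.24, FDFT1 -0.17 and INSIG1 -0.15, and the calls of FDFT1 and INSIG1 were lost on leaving out any of 2 and any of 7 single libraries (adjusted p up to 0.054 and 0.081, edgeR). With the block, 1 cholesterol gene rose and 11 fell. This list was lower by camera (adjusted p = 0.002, but adjusted p = 0.057 with an estimated correlation). Of 44 oxidative phosphorylation genes, 1 rose and 1 fell (1 and 1 adjusted over the list alone), with a median of 0.02: NDUFA6 rose by 0.30, and ATP5F1A gave -0.20, a call lost on leaving out any of 4 single libraries (adjusted p up to 0.064, edgeR). Of 29 glycolysis and hypoxia genes, 2 rose and 4 fell (2 and 4 adjusted over the list alone), with a median of -0.04; the angiogenic factor VEGFA rose by 0.32 and the aldolase ALDOC fell by 0.36. Of 18 heat shock and metallothionein genes, 1 rose and 0 fell (1 rose adjusted over the list alone), with a median of 0.004; the gene that rose, HMOX1 at 0.23, lost its call on leaving out any of 5 single libraries (adjusted p up to 0.085, edgeR). With the block, 3 oxidative phosphorylation genes rose and 3 fell, 5 glycolysis and hypoxia genes rose and 8 fell, and 3 heat shock and metallothionein genes rose and 2 fell. Camera called none of these last 3 lists (adjusted p = 0.726, 0.272 and 0.683, and adjusted p = 0.846, 0.275 and 0.704 with an estimated correlation). Fry called the glycolysis and hypoxia list lower (adjusted p = 0.0045). The tests ask different questions: fry whether a list changed at all, camera whether it changed more than other genes. Of the 26 lists, fry called 23.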

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

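The splits of the libraries, the tests of overlapping genes and of GC content or exon length for odd against even numbers, the test of the whole granule list and the test of dilution were chosen only after those results were seen. In 10 of 230 groups of 4 libraries, a library lay far from the other 3 (gap over range above the critical value), where chance singles out about 1 in 20 groups. These were GDF15 in MOCK replicate 1 (ratio 0.953; 30.5 CPM against 22.2 to 22.6), TNXB in RRM2_OE replicate 1 (0.91; 4.87 against 4.07 to 4.15), PLK1 in MOCK replicate 4 (0.915; 71.1 against 77.9 to 78.6) and in RRM2_OE replicate 3 (0.942; 57.6 against 50.2 to 50.6), and NFKBIZ in RRM2_OE replicate 1 (0.853; 41.4 against 44.0 to 44.5). The others were TAP1 in MOCK replicate 3 (0.891; 70.0 against 61.3 to 62.2), PRF1 in RRM2_OE replicate 1 (0.911; 83.2 against 89.2 to 89.8) and FCRL1 in MOCK replicate 3 (0.845; 1.254 against 0.62 to 0.72). Mean log2 CPM of the cholesterol synthesis list (0.86; 5.81 against 5.86 to 5.87) and of the epithelial, fibroblast and HEK293 list (0.849; 3.40 against 3.55 to 3.58) lay low in RRM2_OE replicate 4.

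Of the 35 splits of the 8 libraries into 4 and 4, 2 gave at least 1962 genes: the real one, with 1962, and odd against even replicate numbers, with 2099. Chance was not excluded by this count, although the odd against even split points to a structure of the samples. Apart from these 2 splits the highest count was 1, also among the 8 splits that part every numbered pair. With replicate number as a block the real comparison gave 2303 genes higher and 2143 lower. With the odd/even term, only the real one of 18 splits gave 4704 genes (highest other 1), and 18 splits are too few for a share under 0.05.

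Odd- and even-numbered libraries differed in both groups, also in their share of mitochondrial counts (8.02% to 9.51% against 6.43% to 7.69%), and the labels name nothing that separates them. A different assignment of reads in same-strand overlaps was argued against, while opposite-strand overlaps were not tested: genes that overlap another on the same strand had odd/even differences 0.977 times those of other genes of like expression (0.904 to 1.04 by bootstrap, 2578 genes). GC content and exon length together accounted for 0.16 of the variance of the odd/even differences, between the 2 bounds set, and stay open. Leaving out mitochondrial genes kept 0.9871 of the odd/even calls but moved the scaled library sizes by at most 0.0064 on the log2 scale, so this test decides nothing, a ruling made after its value was seen. No biological explanation was tested.

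The p53 targets were higher by similar amounts in both sets of libraries: the smaller median was 0.985 times the larger, which argues against a rise confined to 1 set. Each group held 2 odd and 2 even libraries, so an odd/even difference shared by both groups cannot by itself raise the list in RRM2_OE. Bins of GC content, exon length and expression left 0.968 of the median (0.55 of 0.57). No gene (0) went from 0.5 CPM or less in MOCK to 10 CPM or more in RRM2_OE. This argues only against a line with genes absent from MOCK making up much of RRM2_OE. A changed share of cells present in both groups, or a small admixture, would not show in this count and stays open. A response to the construct is the biological explanation that the design gives. The rise could also follow from separate handling or from any other difference between the 2 engineered groups. These cannot be told apart from the construct here.

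The 12 granule genes that fell had medians of -0.59 in replicates 1 and 3 and -0.68 in replicates 2 and 4 (ratio 0.87), but they were picked because they fell over these libraries, so this decides nothing. Over all 26 tested granule genes, which move both ways, the medians were -0.26 and -0.26. Their ratio was 0.987 (-1.0 to 0.995 by bootstrap, where -1.0 stands for opposite signs), so whether the fall differs between the sets stays open. Each group held 2 odd and 2 even libraries, so an odd/even difference shared by both groups cannot by itself lower the list in RRM2_OE. With the odd/even term 6 granule genes rose and 14 fell (camera adjusted p = 2.25e-04, but adjusted p = 0.062 with an estimated correlation). For the 12 that fell, bins of GC content, exon length and expression left 0.971 of the median (-0.61 of -0.63), a value given for those genes and not for the whole list. Dilution by other RNA would lower all granule genes by about the same factor. The SD of log2 fold changes over 24 members at 5 CPM or more was 0.582. The list was already known to move both ways when this test was chosen. The value therefore bears only on dilution as the sole cause, and dilution together with other changes stays open. Maturation of the cells, separate handling or any other difference between the engineered groups may underlie the pattern. These also stay open, since each coincides with the group.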

How the results depend on the processing

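The odd/even term, the subsets of replicates, the sums, the fits without mitochondrial genes and the list tests that join a block or this term with an estimated correlation were chosen after seeing the data. The number of genes higher (1133) became 2303 with the block, 2427 with the odd/even term, 2793 with odd and even sums, 673 on log2(RPKM + 1) without a filter, 530 at an adjusted p below 0.01, 79 at 2-fold and 203 by glmTreat. Genes lower (829) became 2143 with the block, 2277 with the odd/even term, 2724 with the sums, 1330 in replicates 1 and 3, 422 on log2(RPKM + 1), 417 on log2(RPKM + 0.1), 278 on log2(RPKM + 1) without a filter, 281 at 0.01, 19 at 2-fold and 74 by glmTreat. The stricter thresholds call fewer genes by construction. With the odd/even term the typical biological coefficient of variation fell from 7.2% to 2.64%, a smaller spread that lets more genes pass. The cause was not tested for the other settings. Leaving out each library gave 808 to 937 genes higher and 542 (without MOCK replicate 2) to 607 lower. DESeq2, limma-voom, RLE and upper-quartile factors, library sizes only, the low count filters and the fits without mitochondrial genes kept both counts within 1.5 times, and the median of all genes stayed within 0.0104 of 0 in these settings. With an estimated correlation 4 lists were higher and 0 lower, against 15 and 6. This became 9 and 2 with the odd/even term as well (the dNTP supply, p53, repair, G1/S, monocyte, interferon, NF-kB, integrated stress and T and NK lists higher, the KMT2A and MYC lists lower). It became 0 and 0 with the block as well, a test that has little power because the block leaves few residual degrees of freedom. Fry also called the glycolysis and hypoxia list lower (adjusted p = 0.0045). Fry gave the B and plasma list the other direction (adjusted p = 0.01683), and the uncalled oxidative phosphorylation list turned without MOCK replicate 1 (0.8461) and without RRM2_OE replicate 2 (0.9211), within 0.3853 to 0.9211 over the libraries left out; the cause was not tested. The other called lists and their exceptions stand with the results above. Of the 83 named genes none changed direction in a setting where it was tested. On log2(RPKM + 1) and on log2(RPKM + 0.1), 75 kept and 7 lost their call, and the rest did not pass the RPKM filter. Calls were lost for 11 genes on log2(RPKM + 1) without a filter and for 3 with library sizes only (ATP5F1A, INSIG1 and RPS13). CASP6 lost its call in replicates 2 and 4 alone. Of 664 results with a library left out, 39 lost the call, in 8 genes. Depth, at most 11686152 counts per library, left 11500 genes with counts too low to test.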

Other observations

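The comparison of RRM2 with S phase genes, the test of TNF superfamily ligands, the permutations within replicate or odd and even numbers and the test of the cell line were chosen only after those results were seen, as were the genes named in this part. Of 14 tested TNF superfamily ligands, 6 rose and 1 fell, with a median log2 fold change of 0.39. CD70 (1.29), TNFSF9 (1.19), TNFSF4 (1.16) and TNFSF15 (1.12), ligands that co-stimulate lymphocytes, rose with TNFSF10 (0.70) and TNF (0.38), and TNFSF13B fell by 0.30 on the log2 scale. The ligands may have risen as a family (camera p = 0.011 with the odd/even term and an estimated correlation, not adjusted), a hypothesis found and tested on the same data.

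MPO lies on chromosome 17 beside the related peroxidase genes EPX and LPO and near TSPOAP1, and all fell, with log2 fold changes of -1.40, -0.69, -0.89 and -0.99 for MPO, EPX, LPO and TSPOAP1. AZU1, PRTN3 and ELANE adjoin on chromosome 19 and fell, with log2 fold changes of -0.72, -1.20 and -1.06. Neighbouring genes may share their changes: the nearest tested neighbours of 142 fallen genes had a median of -0.07, against -0.003 for neighbours of random genes of like expression (share of draws 1.0e-04, the smallest that 10000 draws can give). Neighbours of 363 risen genes had a median of 0.10 against -0.003 (share 1.0e-04, again the smallest).

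RRM2 rose by 0.17 more on the log2 scale than CCNE2, the highest of the 41 tested G1/S and replication genes, so its rise was not within the range of that list. The SEs were 0.048 for RRM2 and 0.065 for CCNE2, and no p-value was computed for the difference. How much of the rise came from the resident gene stays open. At equal totals of 10994255 counts, 21228 to 21359 genes had a count in MOCK and 21735 to 21896 in RRM2_OE, a gap of 376 that argues against library depth as the cause (2.52% more genes on average, exact permutation p = 0.0286 with all libraries exchanged freely, 0.125 within replicate numbers and 0.0556 within odd and within even numbers, each the smallest that its permutations can give). The rise was 8.74% for lincRNA genes and 1.76% for protein-coding genes. The 11500 genes too low to test together held 18450 ± 284 counts in MOCK and 20720 ± 136 in RRM2_OE (mean ± SD, n = 4).

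All 8 libraries expressed genes that are not commonly described for THP1. CDKN2A, which THP1 is described as having lost from both chromosomes, was at 44.6 to 56.3 CPM. The erythroid and mast cell regulators GATA1 and GATA2 averaged 104 and 546 CPM in MOCK and 105 and 590 CPM in RRM2_OE, the globin gene HBB 324 and 243 CPM, the mast cell protease CPA3 402 and 429 CPM, and HOXB3 148 and 143 CPM. The cells may therefore include or be another line than the labels name, as a hypothesis: the lowest CDKN2A level of 44.6 CPM is far above the level that a lost gene would give. Whether all cells or a share of them were of another line stays open, and no reference profile of THP1 was used here.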
